A study of Mus musculus with 36 samples.

How the data were processed

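Polyadenylated RNA was measured in 36 brain libraries of mice with the Gpt2 genotypes wild type (WT) and knockout (KO). Each genotype was given vehicle or dm-αKG, the dimethyl ester of α-ketoglutarate. The 4 groups were WT with vehicle (WT-Veh, n = 10), WT with dm-αKG (WT-aKG, n = 8), KO with vehicle (KO-Veh, n = 10) and KO with dm-αKG (KO-aKG, n = 8). Per the labels' protocols, mice received 600 mg per kg dm-αKG or vehicle intraperitoneally, tissues were frozen on postnatal day 19, and RNA came from 10 mg of brain. The brain region of the pieces and the sex of the mice are not given in the sources used here. Each library's group was taken from its labels, and each table column was matched to its library by name.

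Per the labels' protocols, oligo-dT primers with a sample barcode and a unique molecular identifier started the cDNA, which was then fragmented by tagmentation and amplified. Per the submitters' processing notes, the tools included Trim Galore 0.6.10, FastQC 0.12.1, HISAT2 2.2.1, SAMtools 1.6, featureCounts 2.0.6 and deepTools, and the builds mm10 and mm39. The notes as used here give these names without roles. Which build gave the counts, whether strand was used and whether the molecular identifiers were collapsed is not given in the sources used here.

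The authors deposited a table of estimated counts per gene and library, written as whole numbers and not normalised. It holds 56184 gene symbols, of which 19498 had no count in any library. The authors also deposited a CPM table of 21637 genes. Multiplying that table by 1 constant per library gave back each library's counts to within 0.51 of a count for 100% of its genes. By that conversion 85.6% to 88.7% of a library's values were whole within 0.02 and the rest were fractional. The counts are therefore rounded, and why some were fractional is not given in the sources used here. The mean counts of mt-Co3 and its nuclear copy Gm28437 (271498 and 271478) are nearly equal, and whether their reads were split between them or counted for both was not tested. The library totals implied by the CPM table lay 0.769% to 0.972% above the sums of the counts. Genes with near-identical copies, overlapping genes and antisense genes are uncertain for these reasons.

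Libraries held 5.77 to 13.3 M counts (median 11.4 M). Mitochondrial ribosomal RNA took 14.1% to 29.8% of them. No 2 libraries of a group had identical values among 146 pairs, and the chi-square per gene between libraries of a group was 9.103 to 214.8, against 1 from sampling noise alone. This excludes repeated sequencing of 1 library and does not show that libraries come from separate animals. Each library was counted as a replicate because the labels call them biological replicates.

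Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (16255 genes), libraries were scaled by TMM, and 1 robust quasi-likelihood model was fitted to all 36 libraries in 4 groups without covariates. Its 5 contrasts were the genotype effect with vehicle, the genotype effect with dm-αKG, the treatment effect in WT, the treatment effect in KO, and the interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, with no fold threshold. Standard errors come from the fitted model, and adjusted p-values are edgeR's unless another tool is named. CPM values given per group are TMM-scaled, as mean ± SD over libraries.

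There were 46 gene lists (pathways, stress responses, cell types and brain regions), all fixed before the data were examined and each with at least 5 members tested. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a contrast. The same test with an estimated correlation and fry, a rotation test of whether a list moves on balance in 1 direction, were alternatives. A list's score in a library is the mean log2 CPM of its members. Scores of 10 lists were compared in 4 contrasts by 2-sided permutation tests, exact where a group had fewer than 10 libraries and with 1e+05 resamples otherwise, adjusted over these 40 tests.

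The genotype effects under the 2 treatments were compared by a slope through the origin over the called genes, with a jackknife over libraries. The same slope was taken with genes chosen on odd-numbered and estimated on even-numbered vehicle libraries, and the reverse. The treatment effect in KO was set against the genotype effect, which shares the KO-Veh libraries, by the share of genes with opposite sign. That share was set beside 50 simulated data sets without a treatment effect in KO and beside estimates from separate KO-Veh libraries.

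Most genes were named by a rule fixed before the data were examined. For each contrast it takes Gpt2 and the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM. Predicted-gene names and sex-linked check genes are left out. It adds up to 4 called members of each list that is called or has at least 3 called members. Not every gene that this rule takes is reported here. Some genes are named outside it, among them Atf4, Asns, Fgf21, Gsr, Herpud1, Bcat1, Il15, Mrps28, Ndufb3 and Bcl6. The choice of these was not fixed before the data were examined. Gene positions are those of GENCODE vM21 on GRCm38, which gave a position for 94.5% of the tested genes.

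The alternatives chosen before the data were examined were no low-count filter, the size factors of DESeq2, DESeq2 1.42.0, limma-voom with quality weights, the replicate number as a block, only the groups compared, Xist as a covariate, 2 surrogate variables from sva 3.50.0, the CPM table with pseudocounts of 1 and 0.1 and without a filter, an adjusted p under 0.01, leaving out genes within 10 Mb of Gpt2, and leaving out each library in turn. After the data were seen, fits were added with 5 region scores as covariates, without libraries high in cerebellum markers, and without libraries under 8 M counts. Regrouped samples were drawn 60 times per contrast. The model was tested on simulated counts with 1.5-fold, 2-fold and 3-fold changes put into 67, 67 and 66 of 16255 genes. In the design of the genotype effect with vehicle it called 47.8%, 73.1% and 93.9% of these, and 10 unchanged genes. The changed genes were drawn from those with a mean of at least 1 CPM, and each gene was simulated independently. The shares called were therefore not measured for fainter genes or for spread that genes share, here and in the other contrasts. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.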

Results

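The series measured gene expression in the brains of 19-day-old mice with and without Gpt2, the mitochondrial alanine transaminase, which forms pyruvate and glutamate from alanine and α-ketoglutarate. Mice of both genotypes received vehicle or dm-αKG, a cell-permeable ester of α-ketoglutarate. There were 10 WT-Veh, 8 WT-aKG, 10 KO-Veh and 8 KO-aKG libraries. Mean totals were 11.7, 11.1, 11.2 and 9.80 M counts, and single libraries held 5.77 to 13.3 M. The submitters call the replicates of a group biological, but no label says whether each came from a separate animal, so p-values measure the spread between these samples.

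Markers of brain regions differed strongly between libraries of the same group. The first principal component carried 42.8% of the variance. The score of the cerebellum list, a mean log2 CPM over 21 markers, ran from 2.14 to 7.70. It lay more than 1 log2 unit above the mean of all libraries in 3 of 10 WT-Veh, 4 of 8 WT-aKG, 1 of 10 KO-Veh and 1 of 8 KO-aKG libraries. Mean cerebellum scores were 4.77 ± 1.87 in WT-Veh and 3.57 ± 1.62 in KO-Veh (SD, n = 10 each; permutation p = 0.124, adjusted p = 0.352). Xist exceeded Ddx3y, a gene of the Y chromosome, in 2 of 10 WT-Veh, 5 of 8 WT-aKG, 2 of 10 KO-Veh and 4 of 8 KO-aKG libraries.

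**Figure D1:**
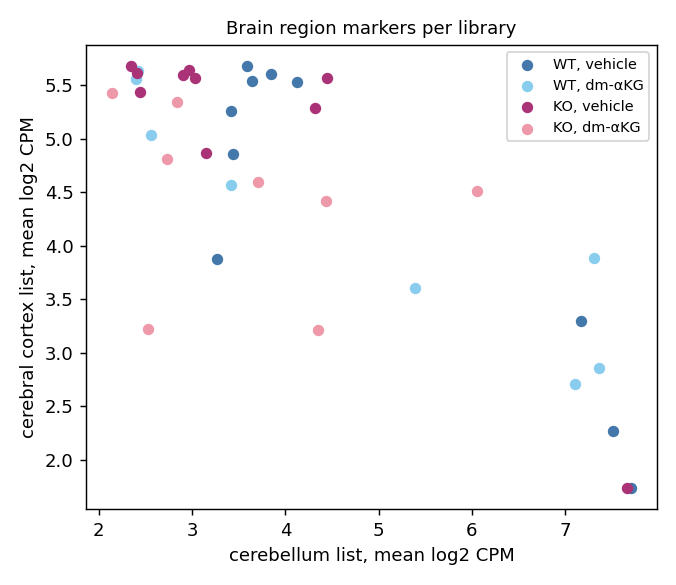
Each point is 1 of the 36 libraries, coloured by group; the x axis is the mean log2 CPM of 21 cerebellum markers and the y axis that of 17 cerebral cortex markers. Libraries range from 2.14 to 7.70 on the x axis, and the group with the most libraries more than 1 unit above the mean is WT-aKG, with 4 of 8.

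Gpt2 lies on chromosome 8 at 85492576 to 85527560 on the plus strand of GRCm38. Its level was 30.2 ± 5.61 CPM in WT-Veh (SD, n = 10), 32.3 ± 3.94 CPM in WT-aKG (n = 8), 2.04 ± 0.837 CPM in KO-Veh (n = 10) and 2.37 ± 0.701 CPM in KO-aKG (n = 8). Single WT libraries ranged from 22 to 39 CPM and single KO libraries from 0.881 to 3.3 CPM, so that every library stood on its label's side. The log2 fold change between genotypes was −3.90 (SE 0.18, edgeR adjusted p = 1.6e-17) with vehicle and −3.77 (SE 0.20, adjusted p = 1.27e-15) with dm-αKG. Knockout libraries still held 10 to 38 Gpt2 counts each. Which part of Gpt2 was deleted is not given in the sources used here, and reads from outside a deleted part check nothing.

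**Figure D2:**
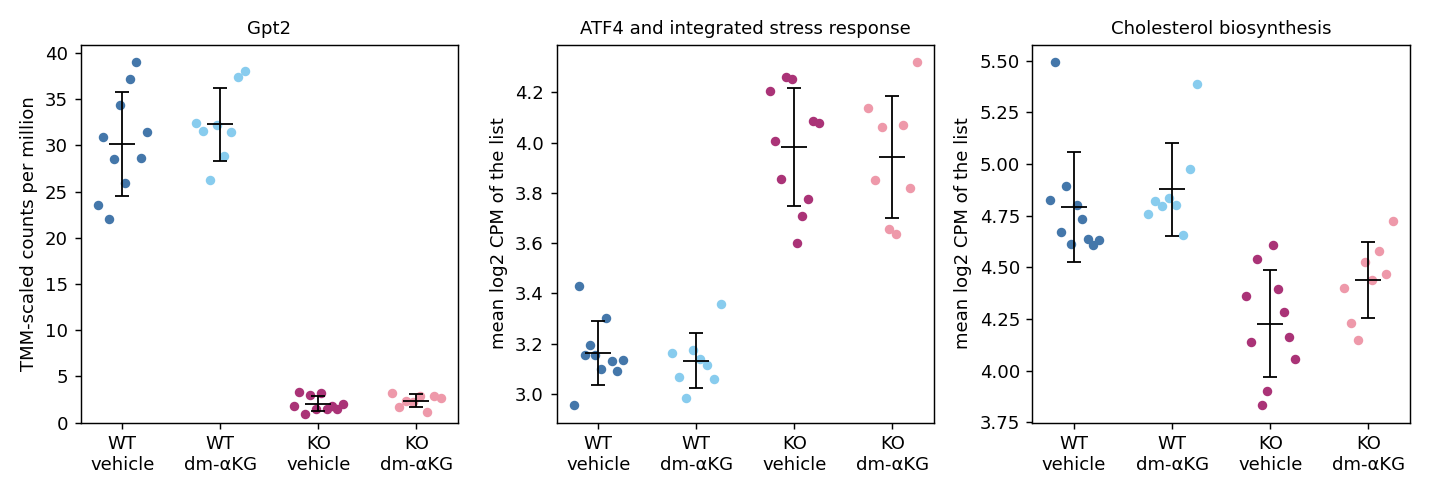
Each point is 1 library, in groups of 10, 8, 10 and 8, with the mean and SD as bars; the panels show Gpt2 in TMM-scaled CPM, and the mean log2 CPM of the list of ATF4 and integrated stress response genes and of the cholesterol biosynthesis list. Gpt2 stays at or below 3.3 CPM in every knockout library, the ATF4 score has means of 3.16, 3.13, 3.98 and 3.94, and the cholesterol score has means of 4.79, 4.88, 4.23 and 4.44.

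Knockouts and wild types were first compared under vehicle, which addresses what loss of Gpt2 changes. Targets of ATF4, the transcription factor of the integrated stress response, rose together: 22 of 35 tested members rose and 1 fell, and that 1 was Gpt2 itself (25 and 1 adjusted over the list alone). Ddit3, which encodes the stress-induced transcription factor CHOP, rose from 13.1 ± 2.62 to 47.5 ± 15.5 CPM (SD, n = 10 per group; log2 fold change 1.85, SE 0.16, edgeR adjusted p = 4.08e-10). Chac1, a glutathione-degrading enzyme, rose from 2.42 ± 1.02 to 19.2 ± 8.97 CPM (log2 fold change 2.98, SE 0.28). Slc7a3, a transporter of cationic amino acids, rose from 6.01 ± 3.08 to 38.6 ± 11 CPM (log2 fold change 2.68, SE 0.28). Genes of cholesterol synthesis fell together, with 14 of 25 lower and 0 higher past the test (22 and 0 adjusted over the list alone).

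The ATF4 list had a median log2 fold change of 0.81 (camera adjusted p = 1.61e-38, and adjusted p = 0.00013 with an estimated correlation). Its score was 3.16 ± 0.13 in WT-Veh and 3.98 ± 0.24 in KO-Veh (SD, n = 10 each), a difference of 0.82 (95% interval 0.64 to 1.00, permutation p = 2e-05). Atf4 itself rose by 0.81 (SE 0.11) on the log2 scale, Asns, the asparagine synthetase, by 1.25 (SE 0.16), Sesn2 by 1.48 (SE 0.22) and the secreted factor Fgf21 by 3.68 (SE 0.71). Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 11 rose and 0 fell (13 adjusted over the list alone; median 0.36, camera adjusted p = 1.44e-19, and adjusted p = 0.00911 with an estimated correlation). Cars1 went from 10.8 ± 1.67 to 22.6 ± 3.42 CPM and Sars1 from 51.3 ± 6.69 to 91.4 ± 16.9 CPM (SD, n = 10 each). Of 20 genes of serine, glycine and one-carbon metabolism 4 rose and 0 fell (5 adjusted over the list alone; camera adjusted p = 0.000552, and adjusted p = 0.0367 with an estimated correlation). Among them were Psph, the last enzyme of serine synthesis (1.40, SE 0.17), and the mitochondrial folate enzymes Mthfd2 (1.81, SE 0.21) and Shmt2 (0.92, SE 0.11). Of 15 p53 targets 5 rose and 0 fell (6 adjusted over the list alone; camera adjusted p = 0.000552, and adjusted p = 0.0225 with an estimated correlation), among them Pmaip1 (0.98, SE 0.20) and Bbc3 (0.73, SE 0.16), which promote apoptosis. Without members that another list also holds, the adjusted p was 0.905 for the serine list and 0.106 for the p53 list.

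Among the 14 cholesterol genes that fell were Stard4, a sterol transfer protein, from 14.4 ± 3.85 to 7.48 ± 1.89 CPM (SD, n = 10 each; log2 fold change −0.94, SE 0.15, edgeR adjusted p = 0.00016), Mvd (−0.76, SE 0.14), Lss (−0.69, SE 0.14) and Fdps (−0.77, SE 0.17), enzymes of the pathway. The list's median was −0.69 (camera adjusted p = 8.42e-19, and adjusted p = 0.0367 with an estimated correlation), and its score was 4.79 ± 0.27 in WT-Veh and 4.23 ± 0.26 in KO-Veh (permutation p = 2e-05). Of 17 genes of fatty acid synthesis 3 fell, Fasn (−0.51, SE 0.09), Scd1 (−0.75, SE 0.20) and Acss2 (−0.46, SE 0.14), and 0 rose (8 and 0 adjusted over the list alone; camera adjusted p = 7.13e-05, but adjusted p = 0.469 with an estimated correlation). Of 26 genes induced by glucocorticoids 9 rose and 0 fell (10 and 1 adjusted over the list alone; camera adjusted p = 1.13e-07, but adjusted p = 0.202 with an estimated correlation). Among them were Fkbp5, a chaperone of the glucocorticoid receptor, from 11.4 ± 4.98 to 33.8 ± 21.6 CPM, and Plin4, a lipid droplet protein, from 0.482 ± 0.25 to 4.69 ± 4.81 CPM (SD, n = 10 each).

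In energy metabolism the glycolytic genes Pkm (−0.46, SE 0.11), Aldoa (−0.37, SE 0.09), Eno1 (−0.43, SE 0.11) and Pgk1 (−0.31, SE 0.09) fell, 4 of 29 in the list with 0 rising (5 and 1 adjusted over the list alone; camera adjusted p = 0.114). Of 35 dioxygenases that use α-ketoglutarate 4 fell and 0 rose, both over all genes and adjusted over the list alone: Kdm2a, Kdm6b, Tet1 and Plod2, with log2 fold changes of −0.32, −0.51, −0.49 and −0.85 (camera adjusted p = 0.0172, but adjusted p = 0.558 with an estimated correlation). Of 48 nuclear genes of oxidative phosphorylation Ndufa9 (0.30, SE 0.08) and Ndufs3 (0.20, SE 0.06) rose and Sdha (−0.29, SE 0.08) fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0485, but adjusted p = 0.778 with an estimated correlation). Of 49 cytosolic ribosomal protein genes Rpl7 and Rpl27 rose (15 adjusted over the list alone; camera adjusted p = 1.12e-13, but adjusted p = 0.558 with an estimated correlation). Eno1, Rpl7, Rpl27 and the heat shock gene Hspa1b share sequence with near-identical copies, and Aldoa has the same values as Gm57854, so the values of these genes are uncertain. The list of alanine and glutamate transaminases was called lower (camera adjusted p = 0.00622, but adjusted p = 0.202 with an estimated correlation) although its median was 0.02 and its mean −0.26; Gpt2 was its only member called over all genes.

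Among genes with a mean of at least 5 CPM, the largest other rises were those of Cox6a2, a subunit of cytochrome c oxidase, from 7.6 ± 4.81 to 76.3 ± 34.6 CPM (SD, n = 10 each; log2 fold change 3.34, SE 0.46, edgeR adjusted p = 7.64e-06), and Mt3, a brain metallothionein, from 89.4 ± 57.1 to 484 ± 132 CPM (2.44, SE 0.27). Mt3 lies 8.63 Mb from Gpt2 on the same chromosome. Cyb5r1 (1.98, SE 0.20), Cort (1.89, SE 0.56), Dleu7 (1.82, SE 0.38) and Eif4ebp1, a repressor of translation initiation (1.59, SE 0.24), also rose. The largest falls after Gpt2, besides Stard4 (−0.94), were Tnc, an extracellular matrix glycoprotein (−2.43, SE 0.47), the astrocyte water channel Aqp4 (−1.22, SE 0.33), Fabp7, a fatty acid binding protein of radial and Bergmann glia (−1.17, SE 0.30), Ocel1 (−1.11, SE 0.31), Cdc42ep1 (−1.07, SE 0.29), Hapln4 (−1.07, SE 0.27), Etv4 (−0.91, SE 0.27) and Hspa1b (−0.89, SE 0.27). Tnc stood at 14.3 ± 16.5 CPM in WT-Veh and 2.64 ± 1.92 CPM in KO-Veh, and Aqp4 at 112 ± 67.1 and 48 ± 28.4 CPM (SD, n = 10 each).

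Camera also called lists of region and cell type markers, but none of these calls held with an estimated correlation. The cerebellum list had a median of −1.10 (0 of 21 members called; camera adjusted p = 0.00264), cerebral cortex 0.57 (adjusted p = 0.0135), striatum 0.73 (adjusted p = 0.00852), choroid plexus −0.95 (adjusted p = 0.000307) and myelin −0.61 (0 of 25 called, 25 lower; adjusted p = 0.00119). With an estimated correlation their adjusted p-values were 0.686, 0.686, 0.686, 0.558 and 0.686. Permutation tests of their scores gave adjusted p-values of 0.352, 0.414, 0.414, 0.204 and 0.406 in turn. Of 22 astrocyte markers Aqp4 and the serine and alanine transporter Slc7a10 (−0.82, SE 0.19) fell (2 adjusted over the list alone; camera adjusted p = 0.00891, but adjusted p = 0.558 with an estimated correlation). Other called members of lists that camera called were Frmd4a of premyelinating oligodendrocytes (−0.41, SE 0.11), Lum of fibroblasts (lower, edgeR adjusted p = 0.0349), Ccnd1 of the cell cycle (−0.55, SE 0.15) and the immediate early genes Jun (−0.60, SE 0.14) and Bdnf (0.70, SE 0.16). With an estimated correlation the adjusted p of these lists was 0.599 for premyelinating oligodendrocytes, 0.595 for mural cells and fibroblasts, 0.558 for the cell cycle and 0.686 for immediate early genes. In cell type and region lists that camera did not call, Npy (1.46), Ramp3 (1.01) and Lcn2 (0.83) rose, and are named after their values were seen.

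In total 701 of 16255 genes were called by edgeR with vehicle, 422 higher and 279 lower in knockouts, 70 of them by more than 2-fold. Of the 46 lists 23 were called, and 5 of these (ATF4, synthetases, serine, cholesterol and p53) held with an estimated correlation. The count ranged from 165 on the CPM table (limma without TMM scaling, 141 higher and 24 lower) to 1784 with 5 region scores as covariates (857 higher and 927 lower). It was 1666 without KO-Veh-7 (715 higher and 951 lower), 440 without KO-Veh-10 and 462 without KO-Veh-4. Fitted on the 2 vehicle groups alone it was 324.

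The same genotypes were then compared under dm-αKG, with 8 libraries each. The ATF4 list was again higher in knockouts: 19 of 35 members rose and Gpt2 fell (24 and 1 adjusted over the list alone; median 0.83, camera adjusted p = 6.95e-35, and adjusted p = 0.000223 with an estimated correlation). Ddit3 stood at 14 ± 1.97 CPM in WT-aKG and 47.3 ± 9.55 CPM in KO-aKG (SD, n = 8 each; log2 fold change 1.76, SE 0.18, edgeR adjusted p = 2.85e-08), and Slc7a3 at 4.81 ± 2.4 and 35.5 ± 9.61 CPM. Of the aminoacyl-tRNA synthetases 12 of 20 rose and 0 fell (14 adjusted over the list alone; median 0.52, camera adjusted p = 1.68e-29, and adjusted p = 0.000729 with an estimated correlation), with Cars1 at 1.29 (SE 0.12), Nars1 at 1.06 (SE 0.13), Yars1 at 0.97 (SE 0.13) and Sars1 at 0.94 (SE 0.11). Of the cholesterol genes 3 of 25 fell, Stard4 (−0.90, SE 0.17), Mvk (−0.54, SE 0.14) and Tm7sf2 (−0.41, SE 0.11), and 0 rose (13 and 0 adjusted over the list alone; median −0.46, camera adjusted p = 3.64e-12, but adjusted p = 0.18 with an estimated correlation and 0.0121 with fry). The cholesterol score was 4.88 ± 0.22 in WT-aKG and 4.44 ± 0.18 in KO-aKG (SD, n = 8 each), a difference of −0.44 (95% interval −0.66 to −0.23, exact permutation p = 0.000311, adjusted p = 0.00207).

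Of the serine list 3 of 20 rose, Mthfd2 (1.80, SE 0.24), Psph (1.07, SE 0.19) and Shmt2 (0.64, SE 0.12), and 0 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.0206, but adjusted p = 0.263 with an estimated correlation). Of the p53 targets Sesn2 (1.47, SE 0.25) and Gdf15 (1.66, SE 0.34), both also in the ATF4 list, rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.0206, but adjusted p = 0.18 with an estimated correlation). Among the α-ketoglutarate-dependent dioxygenases Egln1 (−0.49, SE 0.13) and Tet3 (−0.50, SE 0.13) fell and P4ha2 (0.70, SE 0.19) rose (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.0825). Plin4 was the 1 glucocorticoid-induced gene of 26 that rose (2.65, SE 0.67; 2 adjusted over the list alone; camera adjusted p = 0.00105, but adjusted p = 0.627 with an estimated correlation). Top2a, which acts in cell division, fell by 1.02 on the log2 scale (SE 0.24), from 1.91 ± 0.484 to 0.932 ± 0.191 CPM (n = 8 each).

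Among genes with a mean of at least 5 CPM, the largest rises with dm-αKG included Cox6a2 (3.46, SE 0.52), Chac1 (2.76, SE 0.32), Mt3 (2.28, SE 0.29), Trim66 (1.80, SE 0.31) and Cyb5r1 (1.58, SE 0.22). The neuropeptide genes Pmch (6.17, SE 1.61, edgeR adjusted p = 0.0376) and Hcrt (5.90, SE 1.45, adjusted p = 0.0253), which mark the lateral hypothalamus, also rose, and their SDs in KO-aKG, 141 and 65.6 CPM, exceeded their means of 73.9 and 26.2 CPM (n = 8). The hypothalamus list had a median of 1.33 (2 of 16 called; 4 adjusted over the list alone; camera adjusted p = 7.28e-06, but adjusted p = 0.613 with an estimated correlation) and the cerebellum list one of −1.94 (adjusted p = 9.1e-05, but adjusted p = 0.652 with an estimated correlation). At the same limit of 5 CPM, the largest falls after Gpt2 were those of Ocel1 (−1.36, SE 0.35), the synaptic gene Rims1 (−1.33, SE 0.35) and Fabp7 (−1.32, SE 0.34). Next, besides Stard4, came Plch2 (−1.28, SE 0.34), Emid1 (−1.09, SE 0.27), Plvap, an endothelial protein (−0.94, SE 0.25), Sptb (−0.93, SE 0.25) and Diras2 (−0.89, SE 0.23). Rims1 stood at 173 ± 118 CPM in WT-aKG and 68.8 ± 28.5 CPM in KO-aKG (SD, n = 8 each). With vehicle Rims1, Plch2, Emid1, Sptb and Diras2 were not called (edgeR adjusted p = 0.206, 0.383, 0.879, 0.232 and 0.473), while Ocel1, Fabp7 and Plvap were. The synaptic list had a median of −0.32 (Rims1 called of 29; 5 lower adjusted over the list alone; camera adjusted p = 0.000121, but adjusted p = 0.613 with an estimated correlation).

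edgeR called 304 of 16255 genes with dm-αKG, 182 higher and 122 lower in knockouts, and camera called 18 lists, of which the ATF4 and synthetase lists held with an estimated correlation. The count was 599, with 217 higher and 382 lower, without the 9 libraries high in cerebellum markers, 145 without a low-count filter and 484 with DESeq2. On the CPM table limma without TMM scaling called 218, of which 212 were higher and 6 lower. With edgeR the count fell to 132 without KO-aKG-8, 143 without WT-aKG-6, 162 without KO-aKG-2, 186 without WT-aKG-1 and 192 without KO-aKG-5.

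Both comparisons found largely the same direction of change. Of the 701 genes called with vehicle, 674 (96.1%) had the same sign with dm-αKG, and the correlation across these genes, which are not independent replicates, was 0.908. The overlap of calls was 108 higher and 44 lower genes, against 4.72 and 2.09 for independent lists, and 0 genes were called in opposite directions. No libraries are shared between these comparisons, but in both more wild types than knockouts were high in cerebellum markers. These were 3 of 10 WT-Veh against 1 of 10 KO-Veh libraries, and 4 of 8 WT-aKG against 1 of 8 KO-aKG libraries. Genes that follow region could therefore agree in sign without an effect of Gpt2 loss. Their part in the agreement was not tested. The slope of the effect with dm-αKG on the effect with vehicle was 0.782 (jackknife SE 0.104, 95% interval 0.578 to 0.986). These 701 genes were chosen by their effect with vehicle, which can lower the slope, and the jackknife kept them fixed. The interval therefore does not show a weaker effect with dm-αKG. The slope was 0.909 over 62 genes chosen on odd-numbered and 0.932 over 351 genes chosen on even-numbered vehicle libraries, each estimated on the others. With each gene weighted by its effect in the choosing libraries, a form added after the data were seen, these became 0.948 and 0.976. Over the 304 genes called with dm-αKG the slope was 1.08.

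**Figure D3:**
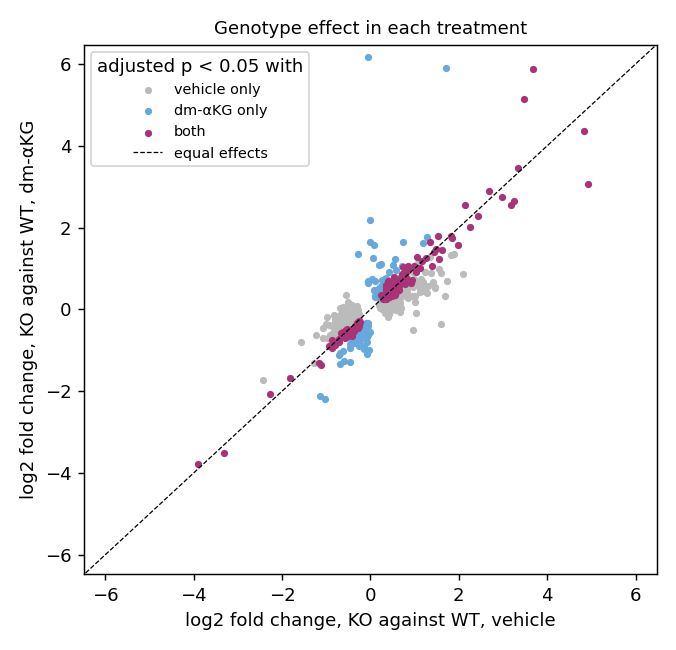
Each point is a gene called by edgeR in at least 1 of the genotype comparisons; the x axis is its log2 fold change, knockout against wild type, with vehicle and the y axis that with dm-αKG, and the dashed line marks equal effects. Of the 701 genes called with vehicle 674 have the same sign on both axes, and 108 genes are called higher and 44 lower in both.

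The treatment comparisons address whether dm-αKG changed expression within a genotype. In wild types (8 treated and 10 vehicle libraries) edgeR called 0 of 16255 genes; 1389 had an unadjusted p under 0.05, against 813 by chance, DESeq2 called 90 and limma-voom 3. The smallest adjusted p was 0.135, for Mrps36, a small mitochondrial protein with a near-identical pseudogene (log2 fold change 0.40, SE 0.08). Of 48 nuclear oxidative phosphorylation genes 41 had higher values with treatment (median 0.27; 0 called, 14 adjusted over the list alone; camera adjusted p = 7.79e-18, but adjusted p = 0.851 with an estimated correlation). All 49 cytosolic ribosomal protein genes had higher values (median 0.22; 0 called in either way; camera adjusted p = 8.22e-17, but adjusted p = 0.886 with an estimated correlation). All 22 immediate early genes had lower values (median −0.43; 1 lower adjusted over the list alone) and 18 of 20 aminoacyl-tRNA synthetases did (median −0.13), with camera adjusted p = 7.76e-05 and 0.00304, but adjusted p = 0.886 for both with an estimated correlation. With 5 region scores as covariates 155 genes were called, 84 higher and 71 lower. In simulated data of this design 37.3% of 1.5-fold, 74.6% of 2-fold and 95.5% of 3-fold changes were called.

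In knockouts (8 treated and 10 vehicle libraries) edgeR called 0 of 16255 genes; 1973 had an unadjusted p under 0.05, against 813 by chance, DESeq2 called 0 and limma-voom 747. The smallest adjusted p was 0.214, for Zfp39. The ATF4 score was 3.98 ± 0.24 in KO-Veh (SD, n = 10) and 3.94 ± 0.24 in KO-aKG (n = 8), a difference of −0.04 (95% interval −0.28 to 0.20, exact permutation p = 0.732, adjusted p = 0.959). The cholesterol score was 4.23 ± 0.26 and 4.44 ± 0.18, a difference of 0.21 (−0.02 to 0.44, exact permutation p = 0.0695, adjusted p = 0.214). The synthetase score differed by −0.02 (−0.17 to 0.13, exact permutation p = 0.767, adjusted p = 0.959).

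Among the region and cell type scores compared between the knockout groups, only the midbrain and hindbrain score had an adjusted p under 0.05. The midbrain and hindbrain score was −0.32 ± 0.54 in KO-Veh (SD, n = 10) and 1.35 ± 1.35 in KO-aKG (n = 8), higher by 1.66 (95% interval 0.69 to 2.63, exact permutation p = 0.0019, adjusted p = 0.0109). The myelin score was higher by 0.80 (0.20 to 1.40, exact permutation p = 0.0105, adjusted p = 0.0525), and all 25 myelin genes had higher values (median 0.85; 0 called in either way; camera adjusted p = 2.62e-11, but adjusted p = 0.527 with an estimated correlation). Of 29 synaptic genes 28 had lower values (median −0.41; 2 adjusted over the list alone; camera adjusted p = 7.82e-09, but adjusted p = 0.273 with an estimated correlation). Of 23 interferon-stimulated genes 21 had higher values (median 0.29; 4 adjusted over the list alone; camera adjusted p = 1.22e-05, but adjusted p = 0.273 with an estimated correlation). Camera called 20 of 46 lists, and 0 held with an estimated correlation. In simulated data of this design 40.3% of 1.5-fold, 73.1% of 2-fold and 93.9% of 3-fold changes were called.

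Whether treatment moved the knockouts' genes back toward wild type was asked of the 701 genes called with vehicle. In 457 of them (65.2%) the treatment effect in KO had the opposite sign to the genotype effect, and the covariance of the log2 values was −0.112. KO-Veh enters both effects with opposite signs, and 50 simulated data sets with the genotype effects as estimated and without a treatment effect in KO gave 69.9% (67.9% to 72.2%) and −0.135 (−0.166 to −0.11). Each used the genes called in it by the same test, 1777 to 2034 genes, more than the 701 observed. With KO-Veh split, the share was 23.5% of 1440 genes called on even-numbered and 49.1% of 159 called on odd-numbered libraries, with covariances of 0.0555 and −0.11. KO-Veh-7, with a cerebellum score of 7.66 (nearest other library of its group 4.45), is among the odd-numbered libraries. The parts thus differ in region markers, so these shares cannot be read as an effect of treatment alone. The observed share lay below all 50 simulated ones. In 60 splits of the real libraries that mix the true groups, the real grouping among them, the share ran from 30% to 89.5% (median 68.2%). The simulated range is far narrower, so it lacks the spread between real libraries and cannot decide whether the observed share is unusual. A share of at least 65.2% came in 35 of the 60 splits, so it was not unusual among these.

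The interaction, which tests whether the treatment effect differed between genotypes, gave 0 called genes with edgeR, DESeq2 and limma-voom; 729 genes had an unadjusted p under 0.05 with edgeR, against 813 by chance. For Gpt2 it was 0.13 (SE 0.26). The ATF4 list had a median of −0.02 (camera adjusted p = 0.536) and the cholesterol list one of 0.20 (adjusted p = 0.0687). Camera called 14 lists, mostly of cell types and regions, and 0 held with an estimated correlation, where the smallest adjusted p was 0.633. In simulated data of this design 8.96% of 1.5-fold, 49.3% of 2-fold and 80.3% of 3-fold changes were called, so changes of the first size would mostly be missed.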

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

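The tests of genes within 10 Mb of Gpt2, of the ATF4 and cholesterol lists against the brain region of the pieces, and of carried-over counts were chosen only after their results were seen, so they are tests and not predictions. Those of genes within 1 Mb of Gpt2, of the myelin list against region and of regrouped samples were written before theirs. At the level used, chance picks out about 1 in 20 groups. Of 224 searches for a single library far from its group 21 picked one out, against 11 by chance.

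Region markers were the widest source of spread, and libraries with unlike marker levels could come from unlike pieces of brain. KO-Veh-7 had a cerebellum score of 7.66 (nearest other library of its group 4.45) and a myelin score of 6.86 (5.8), with Cox6a2 at 5.94 CPM (43.8), Slc7a3 at 13.3 (27), Cort at 0.355 (11.9), Dleu7 at 0.621 (5.8), Kdm6b at 40.4 (28.8) and Plod2 at 7.18 (3.9). With 5 region scores as covariates the ATF4 list kept a median of 0.795 (camera adjusted p = 4.44e-43) and the cholesterol list one of −0.498 (adjusted p = 1.26e-18) with vehicle. The differences that these scores measure therefore do not account for these calls in full. Region differences that the scores miss were not tested, so region stays open as a part of the cause. The myelin list in treated knockouts went from a median of 0.853 to 0.0756, which leaves the region of the pieces open as its cause. Scoring pieces of known region would decide between them.

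Called genes were crowded near Gpt2. With vehicle 16 of 152 genes within 10 Mb were called, and 640 of 15211 elsewhere (odds ratio 2.68, 95% interval 1.48 to 4.54, Fisher p = 0.00079), and with dm-αKG the odds ratio was 3.52 (p = 0.00172). Within 1 Mb it was 3.65 against genes at 1 to 10 Mb with vehicle (p = 0.0259) and 2.65 with dm-αKG (95% interval 0.496 to 13.1, p = 0.222), so both DNA of another strain beside the deleted gene and a local effect of the deletion stay open and may be at work. Mt3, 8.63 Mb away, was at 241 CPM in WT-Veh-3 (nearest other library of its group 106), 243 in WT-aKG-6 (107) and 261 in KO-aKG-5 (431). A recombination between Gpt2 and Mt3 could give such values. KO-aKG-5 held the fewest counts (5.77 M), and KO-Veh libraries went down to 305 CPM, so its value need not stand apart from the knockouts. Genotypes at markers along chromosome 8 in each mouse would decide, and were not analysed here.

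Knockout libraries held Gpt2 at 7.04% of the wild-type mean (SD 2.49, 2.83% to 10.6%). Counts carried over from other libraries, judged by Xist in libraries with Y-linked counts and Ddx3y in the others, reached at most 3.55% (mean 0.961%), and 17 of 18 knockout libraries lay above that. Carry-over at this size would not explain the residue, which may be transcripts from outside the deleted part. Read positions along Gpt2 would decide.

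Other single values far from their group were the cholesterol scores of WT-Veh-2, 5.49 (nearest 4.89), and WT-aKG-8, 5.39 (4.97), and the midbrain and hindbrain score of WT-Veh-2, 4.09 (1.59). In WT-Veh-2 the cholesterol genes Lss and Fdps stood at 23.1 CPM (13.7) and 94.1 CPM (43.5). Cyb5r1 was at 4.34 CPM in WT-Veh-5 (6.29), Lum at 3.33 in KO-Veh-1 (1.61), Jun at 77.4 in WT-Veh-1 (40.9), Trim66 at 0.657 in WT-aKG-3 (1.66) and Sars1 at 58.7 in WT-aKG-8 (48). The cause of these was not tested.

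Camera called 14 lists in the interaction. Their median log2 values were −0.127 for nuclear and −0.493 for mitochondrial-genome oxidative phosphorylation, 0.662 for myelin, 0.44 for premyelinating oligodendrocytes, 0.374 for their precursors, 0.256 for interferon-stimulated genes, 0.838 for choroid plexus, −0.648 for excitatory neurons, −0.274 for synaptic proteins, −0.196 for cytosolic ribosomal proteins, −0.272 for cerebral cortex, 0.558 for thalamus, 0.801 for hypothalamus and 3.04 for midbrain and hindbrain. None held with an estimated correlation (smallest adjusted p = 0.633).

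Each contrast was repeated on 60 splits, the real grouping being 1 of them, that mix the true groups. With vehicle 3 splits called at least the real 701 genes (highest other 2313) and 2 at least the real 23 lists (highest other 25), and with region scores 1 split called at least the real 1784 genes (highest other 1465) and 3 at least the real 19 lists (highest other 21). With dm-αKG it was 1 split for the real 304 genes (highest other 156) and 20 for the real 18 lists (highest other 25). Among the genotype effects fewer than 1 in 20 splits reached the real count for the genes with dm-αKG, the lists with vehicle without region scores and the genes with vehicle given region scores. For the others it was 1 in 20 or more. These shares were not adjusted for the number of comparisons, and the fit with region scores was added after the data were seen, so they do not exclude chance. Outside the genotype effects at least the real number of lists came in 59 splits for the real 4 in WT treatment (highest other 27), 14 for 20 in KO treatment (highest other 24) and 30 for 14 in the interaction (highest other 25). In these contrasts the real gene count was 0, which all 60 splits reach by definition, so the gene counts test nothing there (highest others 3718, 1 and 3259). An opposite share of at least the real 65.2% came in 35 splits (highest other 89.5%). Splits that call several times the real count point to a structure of the samples. With vehicle the splits with 2033 and 2313 genes put all 4 cerebellum-high libraries on 1 side, while the real grouping has 3 in WT-Veh and 1 in KO-Veh.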

How the results depend on the processing

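With vehicle the number of genes called ranged widely, while the direction of the ATF4, synthetase and cholesterol lists did not turn where lists were tested again. Lists were not tested with DESeq2, limma-voom, the CPM table or single libraries left out. In place of 701 genes the count was 348 without a low-count filter, 1177 with limma-voom, 324 from the 2 groups alone, 1483 with 2 surrogate variables, 173, 165 and 197 on the CPM table with pseudocounts of 1, 0.1 and without a filter, 1784 with region scores and 217 at an adjusted p under 0.01. Leaving out single libraries gave 440 to 1666.

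With dm-αKG, in place of 304 genes, the count was 145 without a low-count filter, 484 with DESeq2, 566 with 2 surrogate variables, 552 with region scores, 599 without the cerebellum-high libraries and 96 at an adjusted p under 0.01, and 132 to 360 when leaving out single libraries. For treatment in WT, in place of 0, it was 90 with DESeq2, 3 with limma-voom, 78 with 2 surrogate variables, 1 on the unfiltered CPM table and 155 with region scores. For treatment in KO it was 747 with limma-voom and 0 otherwise. The cause of the difference between limma-voom and the other tools was not tested.

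With the replicate number as a block the counts were 623, 325, 0, 0 and 0, and the camera calls of nuclear oxidative phosphorylation with vehicle (adjusted p = 0.0688), glycolysis with dm-αKG (0.0586) and the TCA cycle for treatment in KO (0.157) were lost. The libraries share only a number: the correlation of same-numbered libraries ran from −0.65 to 0.8, with 25 of 50 pairs over 0.1, and 8 of 36 libraries correlated best with their own number, for which no chance value was computed.

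With an estimated correlation the camera adjusted p was 0.18 for cholesterol with dm-αKG, 0.851 for nuclear oxidative phosphorylation and 0.886 for ribosomal proteins for treatment in WT, and 0.527 for myelin and 0.273 for synaptic proteins for treatment in KO. With fry it was 0.0121, 0.284, 0.856, 0.267 and 0.0656 for these lists in turn.

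With 5 region scores the lists that turned direction were myelin with vehicle (adjusted p = 0.622), for treatment in KO cholesterol (0.715), fatty acid synthesis (0.377), premyelinating oligodendrocytes (0.677), oligodendrocyte precursors (0.118), excitatory neurons (0.791) and immediate early genes (0.0821), and in the interaction myelin (0.0668), precursors (0.979) and excitatory neurons (0.764). Myelin for treatment in KO kept its direction at 0.66. Region lists were not tested with region scores, since the scores are made of them.

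With 2 surrogate variables those that turned were, for treatment in KO, fatty acid synthesis (adjusted p = 0.906), precursors (0.479), immediate early genes (0.886) and hypothalamus (0.923), and in the interaction myelin (0.787), excitatory neurons (0.847), cerebral cortex (0.824) and hypothalamus (0.847). Myelin for treatment in KO kept its direction at 0.116. Without the cerebellum-high libraries ribosomal proteins (0.559) and cerebellum (0.0328) turned with dm-αKG.

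The slope of 0.782 became 1.08 over the genes called with dm-αKG, and 0.909 and 0.932 over genes chosen on the odd-numbered and the even-numbered vehicle libraries. The opposite share of 65.2% became 23.5% and 49.1% with KO-Veh split, where only the odd-numbered part holds KO-Veh-7, which is high in cerebellum markers. Gpt2 kept its fall in all 50 alternatives with vehicle and all 50 with dm-αKG. Named genes were tested in 14 settings, without leaving out single libraries, and none turned direction there. In 1002 values the gene stayed called, and in 334 its adjusted p no longer lay under 0.05. Of these lost calls 14 came with region scores, 26 without the cerebellum-high libraries, and 49, 49 and 55 on the CPM table with pseudocounts of 1, 0.1 and without a filter.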

Other observations

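Members of the ATF4 list that rose in the knockouts under both treatments include the amino acid transporter Slc7a3 and the secreted factors Fgf21 and Gdf15. In knockouts given vehicle Gdf15 was higher by 1.35 on the log2 scale (SE 0.30), and with dm-αKG by 1.66 (SE 0.34). Between knockouts given dm-αKG and vehicle (n = 8 and 10) the log2 difference was −0.02 for Atf4, −0.003 for Ddit3, −0.41 for Chac1, −0.64 for Eif4ebp1 and −0.25 for Shmt2. None of these passed the test over all genes (edgeR adjusted p = 0.959, 0.994, 0.555, 0.304 and 0.378).

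The NRF2 target Gsr, glutathione reductase, fell in the knockouts with vehicle (−0.57, edgeR adjusted p = 0.0197) and with dm-αKG (−0.69, adjusted p = 0.0201), beside the rise of Chac1. Herpud1 of the endoplasmic reticulum stress response rose by 0.71 and 0.70, and lies 8.86 Mb from Gpt2. Bcat1, which transfers amino groups between branched-chain amino acids and α-ketoglutarate, rose with dm-αKG (0.97, adjusted p = 0.0076). Il15, a cytokine gene 3.09 Mb from Gpt2, rose by 1.17 with vehicle and 1.19 with dm-αKG.

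Whether knockouts with a higher ATF4 score have a lower cholesterol score was a test written before the correlation was seen. Across 18 knockout libraries Spearman's rho was −0.364 (permutation p = 0.137). In KO-Veh alone it was −0.794 (n = 10, p = 0.00922, adjusted p = 0.0277), and in KO-aKG 0.214 (n = 8, exact p = 0.619). Pearson's r in KO-aKG went from 0.237 to −0.23 without the 2 farthest libraries. The prediction needed p under 0.05 across all knockouts and a negative value under each treatment, and failed on both. The difference between the groups was not tested.

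In wild types given dm-αKG the ribosomal and nuclear oxidative phosphorylation lists had higher values, with 0 members called and adjusted p = 0.886 and 0.851 with an estimated correlation, and 59 of 60 splits called at least as many lists. With region scores as covariates, a fit chosen after the data were seen, 155 genes were called. Among them were the mitochondrial ribosome gene Mrps28 (0.43, adjusted p = 0.00428) and the complex I gene Ndufb3 (0.35, adjusted p = 0.0134), both higher, and Bcl6 (−0.58, adjusted p = 0.00846), lower. This may reflect treatment, or RNA quality, handling or region differences that the scores do not remove. These other causes were not tested. Sex markers also differed between these groups: Xist exceeded Ddx3y in 2 of 10 WT-Veh and 5 of 8 WT-aKG libraries, and the fit with region scores had no term for them. With Xist as a covariate and no region scores edgeR called 0 genes. Without the covariates edgeR called 0 genes and DESeq2 90.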
